A study of Mus musculus with 32 samples.

How the data were processed

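Total RNA of 26 mouse tumours and 6 normal reproductive tissues was sequenced, and a pair of gene tables with 55450 genes each was used. RSEM expected counts, which divide reads shared between genes in proportion, were deposited by the authors, and per the submitters' processing notes the tools were Picard, bcl2fastq, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.1 with the mouse builds mm10 and GRCm38. The TPM values (counts divided by gene length and scaled to a fixed sum) were also deposited by the authors and come from RSEM, per the submitters' processing notes. The strandedness of the counting is not given in the sources used here. All columns were mapped to samples (0 left unmapped). Gene IDs matched GENCODE M21 (GRCm38) for 55450 of 55450 genes, which gave the coordinates.

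Libraries were grouped by their labels into 10 groups. Titles carry different animal numbers within each group. The labels do not say from which GEMM tumour an allograft came, so allografts of a model may share a source, and their spread may then be smaller than that between animals. The normal ovary and oviduct come from the same 3 animals. The chosen fit did not use the animal as a block and so ignores this pairing, and the fit with this block is an alternative. Deviations from the tissue mean correlated between the tissues of an animal at -0.084, -0.044 and 0.06. Pairs of libraries within groups were checked for duplicates by the chi-square per degree of freedom of their counts, and the lowest of 39 pairs was 10.9, far above the value of 1 that resequencing of the same library gives.

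Expected counts were rounded and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and filterByExpr (minimum count 10, minimum total 15). Normal tissues were compared in a fit of 6 libraries (17334 genes, 99.87% of counts, normalization factors 0.968 to 1.03). Tumours were compared in a fit of 26 libraries (20000 genes, 99.94%, 0.894 to 1.12), and tumours with normal tissue in a fit of all 32 (20887 genes, 99.95%, 0.891 to 1.12). A gene was called at a Benjamini-Hochberg adjusted p < 0.05. Oviduct-origin is the mean of the Ad-BPR, Pax8-BPR and Ovgp1-BPR groups with equal weights on the log scale. The standard error of a log2 fold change is its size divided by the square root of F. CPM given with a comparison come from that comparison's own fit, and group levels with their standard deviations from all 32 libraries. Where every library of an arm had a count of 0, the fold is a lower bound against a floor of 3 counts per library. Where an arm held 1 to 3 counts in all, only levels are given.

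The 25 gene lists are cell cycle and E2F targets, homologous recombination and Fanconi repair, p53 targets, high-grade serous carcinoma epithelial markers, oviduct secretory cells, ciliated cells, ovarian surface epithelium and mesothelium, granulosa with theca and luteal cells, oocyte, smooth muscle, fibroblast and extracellular matrix, epithelial-mesenchymal transition factors, T and NK cells, B and plasma cells, macrophages, neutrophils, interferon response, antigen presentation, endothelium, hypoxia and glycolysis, adipocytes, skeletal muscle, pancreatic acinar cells, erythroid cells and human ovarian carcinoma subtype markers. The hypoxia list has 15 symbols and 16 tested genes, because Aldoa has a pair of gene IDs. Lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera asks whether a list moves more than the other genes. The self-contained test fry asks, in its directional form, whether a list moves one way at all, and in its mixed form whether its genes change in any direction. Member counts are given as adjusted over all tested genes and over the list alone.

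Genes named in the comparisons follow a fixed rule. The first part takes the largest fold changes among called genes with at least 10 CPM in the higher arm and no overlap between arms, 8 per direction for comparisons with normal tissue, of origin and across models and 5 for the others. Predicted genes and receptor or antibody segments are counted and not named. Some genes that meet the rule are not reported here. The next part takes up to 4 called members of a list in its main direction and up to 2 against it, and the last takes Brca1, Trp53, Rb1, Cdkn2a, Krt18, Pax8, Ovgp1 and Wt1 whatever their value. Comparisons, tests, lists, this rule and the alternatives were chosen before the data were examined, except where the closing part says otherwise.

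Similarity was measured by Spearman correlation of log2 CPM (prior count 2), and the difference within against between models was tested with 1e+05 one-sided permutations of the model labels. Principal components were computed on the centred log2 CPM of the 20000 genes. Alternatives were DESeq2 1.42.0, edgeR with RLE factors, limma on log2(TPM + 1), limma voom with quality weights, no filter on low counts, fits of only the groups compared, oviduct-origin models pooled as 1 group, and leaving out each library. Figures were drawn with matplotlib 3.10.9.

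The method was tested on simulated data with the libraries and spread of each comparison, in which 200 genes were changed, 67 by 2-fold, 67 by 4-fold and 66 by 16-fold. Recovery at these 3 sizes was 65.7, 88.1 and 100% for normal oviduct against ovary (17334 genes), 23.9, 56.7 and 87.9% for OSE-BPR GEMM against ovary (20887 genes) and 34.3, 56.7 and 87.9% for oviduct-origin GEMM against oviduct (20887 genes). All others were simulated with 20000 genes. It was 22.4, 70.1 and 77.3% for origin in GEMM, 47.8, 68.7 and 84.8% for origin in allografts, and 11.9, 56.7 and 84.8% for the change of the origin difference. It was 10.4, 50.7 and 78.8% for Pax8-BPR against Ad-BPR, 11.9, 65.7 and 83.3% for Ovgp1-BPR against Pax8-BPR, and 7.46, 50.7 and 71.2% for Ovgp1-BPR against Ad-BPR. For allograft against GEMM it was 14.9, 67.2 and 89.4% in OSE-BPR, 10.4, 49.3 and 63.6% in Ad-BPR, 2.99, 41.8 and 69.7% in Pax8-BPR, 7.46, 53.7 and 81.8% in Ovgp1-BPR, and 61.2, 82.1 and 97% across the models. Unchanged genes called numbered 0 to 11 per comparison. Only 200 genes were changed, whereas comparisons with any call in the data called 10.4 to 53% of the genes. The adjusted p is stricter when few genes change, so the recovery given is not the sensitivity of those comparisons. The changed genes were drawn only from genes above a minimum mean CPM, so recovery among genes at lower levels was not measured.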

Results

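The data describe 32 RNA sequencing libraries from female mice in 10 groups, 26 from tumours and 6 from normal tissue. Primary tumours of a genetically engineered mouse model (GEMM, a tumour that arose in the engineered animal itself) gave 12 libraries, and allografts (tumours grown after transfer to another animal) gave 14. The 4 tumour models share loss of Brca1, an altered Trp53 and the K18GT121 transgene, which inhibits Rb, and they differ in the cell that was targeted. OSE-BPR was started from the ovarian surface epithelium by adenoviral Cre recombinase placed under the ovarian bursa (3 GEMM tumours, 5 allografts, FVB strain). Ad-BPR was started from the oviduct by adenoviral Cre placed in its lumen (2 GEMM tumours, 4 allografts). Pax8-BPR used a tamoxifen-activated Cre driven by Pax8 in oviduct secretory cells (4 GEMM tumours, 2 allografts), and Ovgp1-BPR used an inducible Cre driven by Ovgp1, with the Trp53 mutation R172H by its sample labels (3 GEMM tumours, 3 allografts). The series description names this mutation too but lists a floxed Trp53 in the genotype of that model, a conflict left open here. The last 3 models, called oviduct-origin here, and the normal ovary (n = 3) and normal oviduct (n = 3) are C57Bl/6 by label. Assigned counts per library ran from 13.99 M to 20.51 M with a median of 17.43 M.

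Trp53 (GRCm38 chromosome 11, 69580359 to 69591873, ENSMUSG00000059552.13), the tumour suppressor gene targeted in every model, was read first. Its level was 117 ± 4.09 CPM (counts scaled to the same library total, mean ± standard deviation) in normal ovary and 87.7 ± 6.06 in normal oviduct. It was 11.8 ± 3.14 in OSE-BPR GEMM and 12.8 ± 2.32 in OSE-BPR allografts, 15.7 ± 1.47 and 19.2 ± 1.99 in Ad-BPR, and 30.1 ± 9.11 and 15.7 ± 3.85 in Pax8-BPR. Ovgp1-BPR tumours stayed at the level of normal tissue, with 128 ± 27.1 in GEMM and 125 ± 25.9 in allografts, so the lowest of these 6 tumours (101 CPM) lay above the highest of the other 20 (43 CPM). Brca1 (chromosome 11, 101488764 to 101551955, ENSMUSG00000017146.12), needed for repair of DNA breaks by homologous recombination, stood at 22.8 ± 5.59 in OSE-BPR GEMM, 27.2 ± 6.78 in OSE-BPR allografts, 33.9 ± 18 and 32.4 ± 4.69 in Ad-BPR, 46.7 ± 25.9 and 44.8 ± 11.8 in Pax8-BPR, and 39.8 ± 9.43 and 31.4 ± 6.7 in Ovgp1-BPR, against 17.2 ± 4.63 in ovary and 4 ± 1.71 in oviduct. Gene totals do not separate reads inside the floxed part of Brca1 or Trp53 from reads outside it, and reads outside the deleted part check nothing, so these values do not show whether either gene was deleted.

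Rb1 (chromosome 14, 73183673 to 73325822), the gene of the protein the transgene acts on, lay between 22 and 46.2 CPM as a mean in the 8 tumour groups and at 23.8 in both normal tissues. Cdkn2a (chromosome 4, 89274471 to 89294653, ENSMUSG00000044303.6), which encodes a cell cycle inhibitor that accumulates when Rb is disabled, reached 105 to 319 CPM in the 26 tumours and at most 1.03 in the 6 normal libraries. Krt18, a simple-epithelium keratin whose promoter drives the transgene, was at 462 to 1170 CPM in the tumour group means, 317 ± 56.2 in oviduct and 12.1 ± 1.95 in ovary. Pax8 (chromosome 2, 24420560 to 24475599, ENSMUSG00000026976.15), a transcription factor of oviduct secretory cells, was at most 2.12 CPM in the 8 OSE-BPR tumours and 19.6 to 207 in the 18 oviduct-origin tumours. Wt1 (chromosome 2, 105126529 to 105173616), a factor of the coelomic epithelium, was 881 ± 232 in OSE-BPR GEMM and 665 ± 37.9 in Ovgp1-BPR GEMM, against 254 ± 37 in Ad-BPR and 203 ± 133 in Pax8-BPR GEMM. Epcam, an adhesion molecule of epithelia, was 83 ± 103 in Ovgp1-BPR GEMM and 157 ± 269 in its allografts, the lowest of the tumour groups, whose other means lay between 449 and 1090. The Ovgp1-BPR means rest on single tumours, as GEMM replicates 1 to 3 stood at 200, 45.7 and 3.63 CPM and allograft replicates 1 to 3 at 2.8, 0.466 and 467. Xist, the X-inactivation RNA of female cells, was present in every tumour at 113 to 5920 CPM.

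**Figure D1:**
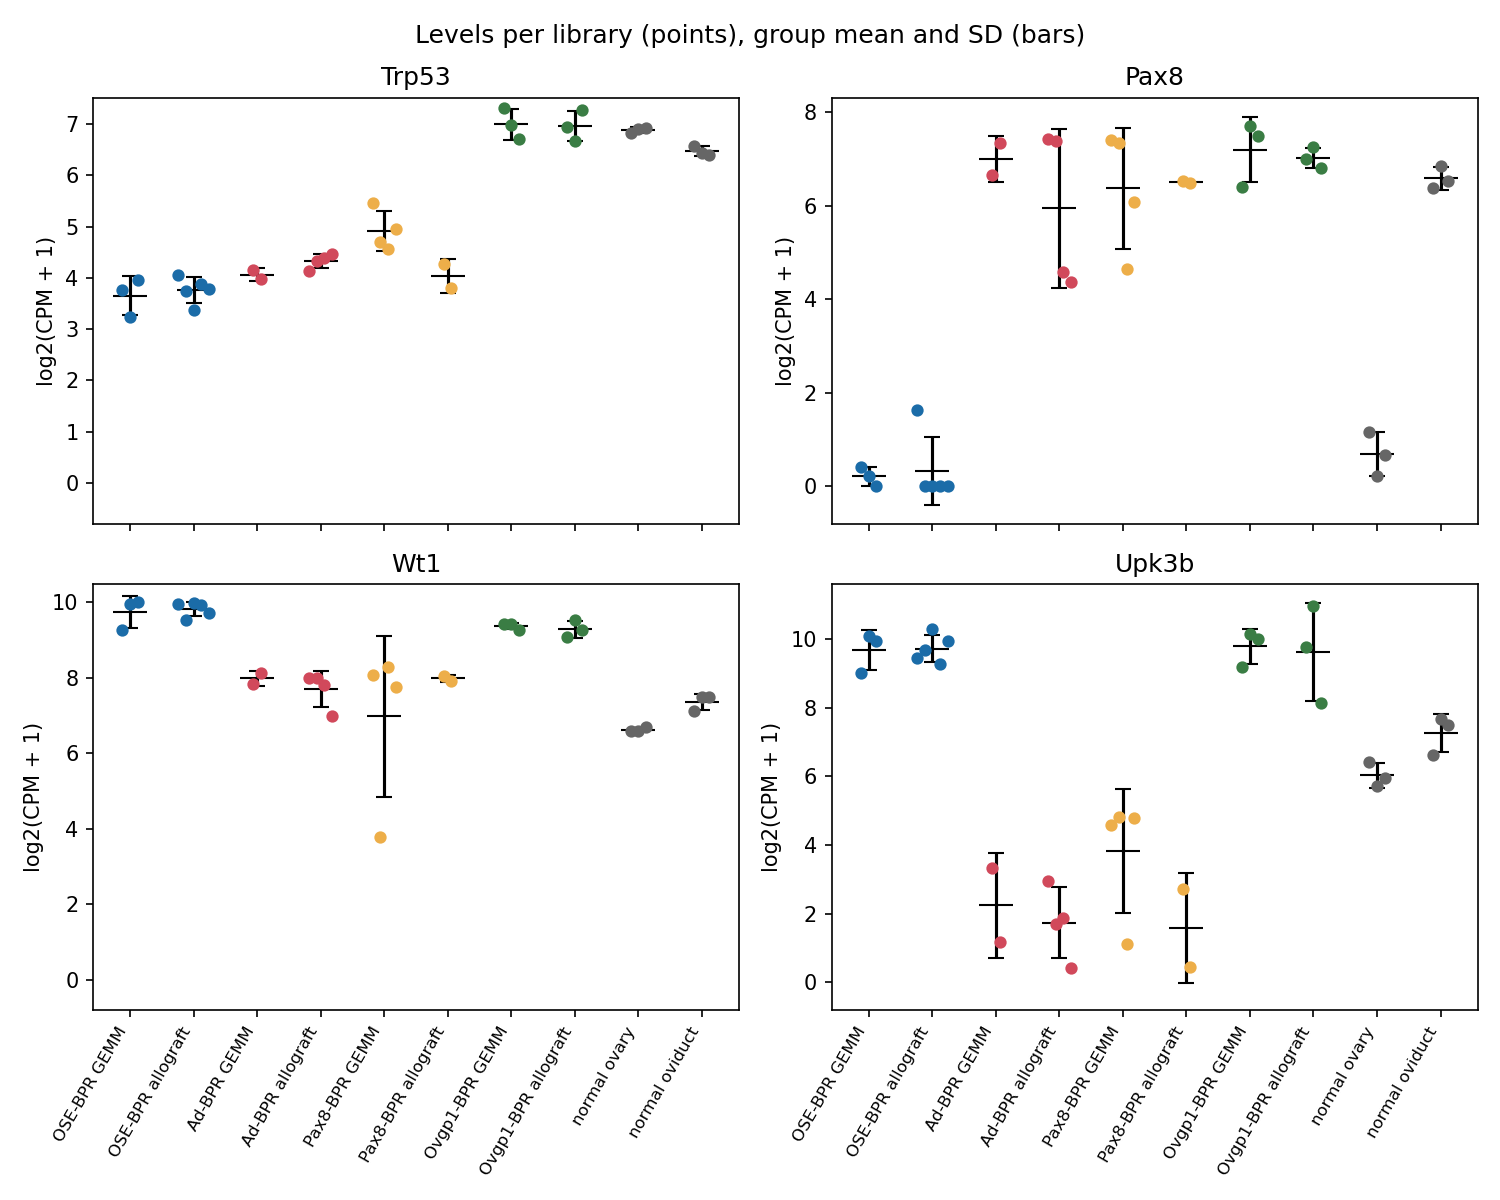
Levels of Trp53, Pax8, Wt1 and Upk3b in each library as log2(CPM + 1), by group, with bars for mean ± standard deviation (n per group 2 to 5).

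The first question was whether tumours resemble others of their own model more than tumours of the other models. Among the 12 GEMM tumours the mean Spearman correlation over 20000 genes was 0.935 within models and 0.864 between models, a difference of 0.0711 (permutation of the model labels, p = 0.00012). Among the 14 allografts the values were 0.949 and 0.861, a difference of 0.0885 (permutation p = 1e-05, the smallest possible with these permutations). Allografts of a model may share a source, in which case this p treats related tumours as independent. Ad-BPR and Pax8-BPR tumours were close to each other (mean correlation 0.934). Pax8-BPR tumours correlated at a mean of 0.925 among themselves, so this model was on average no closer to itself than to Ad-BPR. Ovgp1-BPR tumours stood nearer on average to OSE-BPR (mean 0.89, highest pair 0.93) than to Ad-BPR (0.865, highest 0.933) or Pax8-BPR (0.861, highest 0.935). For all 8 OSE-BPR, 6 Ad-BPR and 6 Ovgp1-BPR tumours the closest other tumour was of the same model. This held for 2 of the 6 Pax8-BPR tumours, and the nearest neighbour of the other Pax8-BPR tumours was an Ad-BPR tumour. Allografts may stem from the GEMM tumours, so a nearest tumour may be a graft of the same tumour. Ovgp1-BPR GEMM replicates 1, 2 and 3 paired with allograft replicates 3, 2 and 1 as mutual nearest tumours (0.969, 0.97 and 0.978). The first principal component held 44% of the variance and placed OSE-BPR at -168 to -101, Ovgp1-BPR at -82.8 to 24.6, Pax8-BPR at 75.3 to 123 and Ad-BPR at 115 to 128. The second component (13.7%) set Ovgp1-BPR (-140 to -32) apart from the other 3 models (0.432 to 72.5). Ovgp1-BPR GEMM replicate 1 (first component -18.3) and allograft replicate 3 (24.6) stood apart from the other 4 Ovgp1-BPR tumours (-82.8 to -58.7), and the second nearest tumour to that allograft was Pax8-BPR GEMM replicate 4 (0.935).

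**Figure D2:**
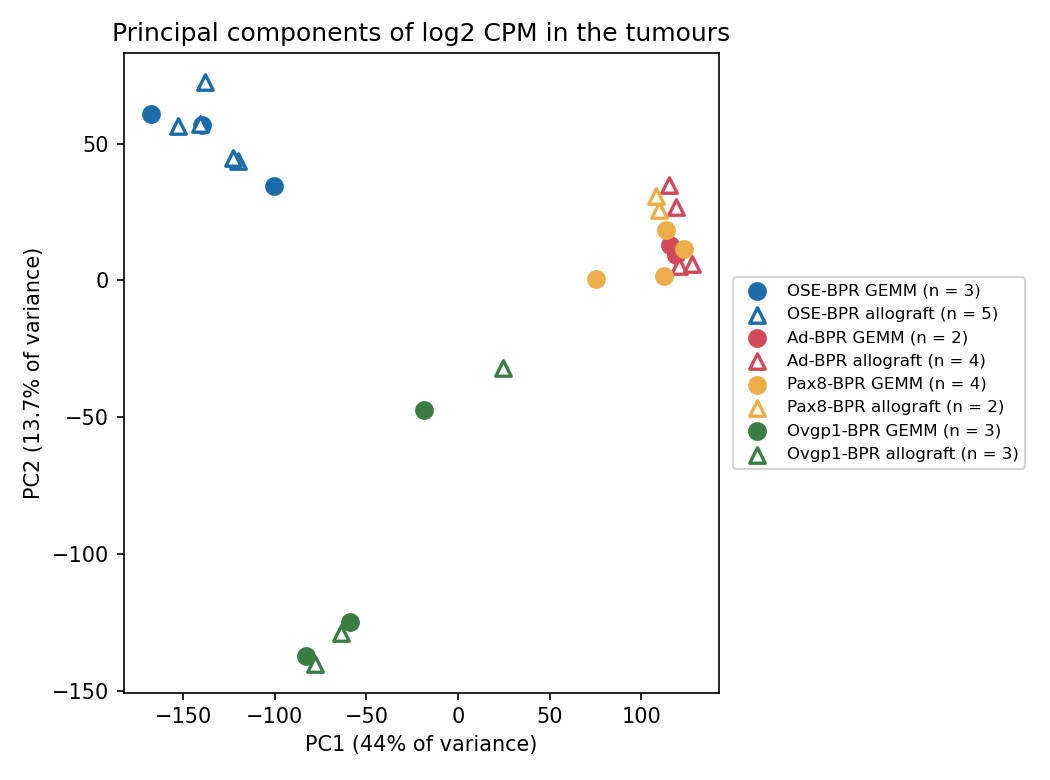
First and second principal components of the 26 tumour libraries, by model and by GEMM or allograft.

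The comparison of normal oviduct (n = 3) with normal ovary (n = 3) asked which genes mark the tissues in which the models were started. Ltf, encoding the secreted iron-binding protein lactoferrin, was higher in oviduct by a log2 fold change of 11.80 ± 0.50 (standard error, as throughout the comparisons; edgeR adjusted p = 7.9e-06, 1560 against 0.417 CPM). Ovgp1 (chromosome 3, 105973711 to 105987423), which encodes the oviduct glycoprotein, rose by 11.02 ± 0.51 (adjusted p = 1e-05) and Pax8 by 7.29 ± 0.38 (adjusted p = 1.5e-05). Dcpp1, a secreted protein of the oviduct, had no count in the 3 ovary libraries and was at least 1040-fold higher in oviduct (185 CPM). Cyp19a1, the aromatase of granulosa cells, fell by 5.74 ± 0.83 on the log2 scale (adjusted p = 0.0013, 1.74 against 88.1 CPM), and Inhba, an inhibin and activin subunit, by 5.12 ± 0.63 (adjusted p = 0.00059).

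Oviduct replicates 1 and 3 also carried transcripts of ovarian cells, so the folds of ovary genes depend on them, as for Cyp19a1 (4.02, 0.156 and 0.77 CPM in replicates 1 to 3, from the fit of all 32 libraries) and Inhba (20.9, 3.38 and 11). edgeR called 9191 of 17334 genes between the normal tissues at adjusted p < 0.05, 4946 higher and 4245 lower in oviduct, against 2605 in a fit of all 32 libraries. Leaving out normal oviduct replicates 1 and 3 leaves 1 oviduct library, with all spread taken from the ovaries, so no count is given for it. The share higher was 53.8%, and 42.4% when limma was run on TPM. The median log2 fold change of all genes was -0.11 with limma on TPM and 0.017 in the chosen fit. Of the 21 ciliated cell genes tested, 20 rose and 1 fell (the same counts adjusted over the list alone), with Cfap43 at 7.17 ± 0.22 and Tekt1 at 6.00 ± 0.20, while Ccno, needed for the centrioles of cilia and also expressed in oocytes, fell by 1.56 ± 0.33. The list was higher by camera (adjusted p = 1.17e-08, adjusted p = 0.515 with an estimated correlation). All 8 oviduct secretory genes rose (8 adjusted over the list alone), among them Wfdc2 (7.57 ± 0.24) and Emx2 (2.03 ± 0.09), with camera adjusted p = 1.32e-05 (adjusted p = 0.13 with an estimated correlation). Of 12 smooth muscle genes 11 rose (11 over the list alone), such as Des (3.76 ± 0.18) and Smtn (1.96 ± 0.08), with camera adjusted p = 1.12e-07 (adjusted p = 0.452 with an estimated correlation). In the ovary direction, 15 of 18 granulosa, theca and luteal genes were lower in oviduct (16 over the list alone), including Star (-4.34 ± 0.60) and Foxl2 (-1.88 ± 0.24), and the list passed at camera adjusted p = 1.17e-05 (adjusted p = 0.515 with an estimated correlation). Of 35 cell cycle and E2F target genes 33 were lower in oviduct (33 over the list alone), such as Ccne2 (-2.33 ± 0.37) and E2f7 (-1.62 ± 0.25), with camera adjusted p = 6.85e-09 (adjusted p = 0.515 with an estimated correlation). Of 8 lists called by camera, 0 stayed called with an estimated correlation. Pancreatic acinar genes (4 tested, median log2 fold change -0.88, adjusted p = 0.387) did not pass.

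OSE-BPR GEMM tumours (n = 3) were set against normal ovary (n = 3) to ask what distinguishes these tumours from the organ that carries their cell of origin. Cdkn2a was higher by 7.85 ± 0.45 (adjusted p = 2.3e-11, 217 against 0.931 CPM) and Trp53 lower, at -3.31 ± 0.26 (adjusted p = 9.1e-09). Krt18 rose by 5.47 ± 0.60 (adjusted p = 1.6e-06) and Wt1 by 3.17 ± 0.56 (adjusted p = 0.00028). Zim1, an imprinted zinc-finger gene, rose by 8.22 ± 1.39 (adjusted p = 0.00019, 376 against 1.26 CPM), and Tdh, a threonine dehydrogenase, by 9.07 ± 1.52 (adjusted p = 0.00021). Cyp11a1, the first enzyme of steroid synthesis, was at 0.847 CPM against 5480 in ovary (-12.68 ± 2.12, adjusted p = 0.00017), and Lhcgr, the luteinizing hormone receptor, had no count in the tumours and was at least 2120-fold lower than in ovary. Brca1 (0.40 ± 0.40, adjusted p = 0.51) and Rb1 (0.28 ± 0.30, adjusted p = 0.54) were not called.

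edgeR called 4842 of 20887 genes for OSE-BPR GEMM against ovary, 2414 higher and 2428 lower. The tumours are FVB and the ovaries C57Bl/6, so tumour and strain differences cannot be separated here. The control is ovary tissue and not the surface epithelium alone. Falls of steroid synthesis, hormone receptor, oocyte and adipocyte genes therefore cannot be told apart from a difference in cell make-up. The count was 3114 without normal ovary replicate 2 and 3220 without OSE-BPR GEMM replicate 3. Of 35 cell cycle and E2F genes 24 rose (29 over the list alone), including E2f8 (2.39 ± 0.34) and Cdt1 (2.29 ± 0.33), with camera adjusted p = 4.7e-15 (adjusted p = 0.128 with an estimated correlation). Of 20 homologous recombination and Fanconi repair genes 12 rose (12 over the list alone), such as Rad54b (2.50 ± 0.34), with camera adjusted p = 4.82e-07 (adjusted p = 0.17 with an estimated correlation). Ovarian surface epithelium and mesothelium genes included 9 of 13 that rose (10 over the list alone), among them Rspo1 (4.33 ± 0.79) and Upk3b (3.71 ± 0.95), with camera adjusted p = 1.47e-05 (adjusted p = 0.0992 with an estimated correlation). Oocyte genes fell in 17 of 19 cases (18 over the list alone), with Zp1 without a count in the tumours and at least 164-fold lower. Their median log2 fold change was -8.41, or -7.06 with such genes at their bounds, and camera gave adjusted p = 3.56e-19 (adjusted p = 0.0992 with an estimated correlation). Of 16 hypoxia and glycolysis genes 8 rose (10 over the list alone), with Egln3 at 4.03 ± 0.68 and Car9 at 4.17 ± 0.89 (camera adjusted p = 0.000239, adjusted p = 0.244 with an estimated correlation). Adipocyte genes fell in 9 of 10 cases (9 over the list alone), for example Plin1 (-8.13 ± 2.25), with camera adjusted p = 0.000389 (adjusted p = 0.257 with an estimated correlation). The p53 target list did not pass (adjusted p = 0.262), with 2 genes up (Btg2, 1.62 ± 0.39, and Pmaip1) and 4 down, such as Zmat3 (-1.57 ± 0.22). Camera called 14 of 25 lists, and 0 of these with an estimated correlation.

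Oviduct-origin GEMM tumours (n = 9, the 3 models weighted equally) were set against normal oviduct (n = 3) to ask what separates them from the organ they arose in. Cdkn2a was higher by 8.52 ± 0.45 (adjusted p = 4.6e-13, 224 against 0.596 CPM). Brca1, low in normal oviduct, was higher by 3.31 ± 0.41 (adjusted p = 1.1e-06). Ovgp1 fell from 6830 to 99.6 CPM (-8.21 ± 0.84, adjusted p = 6.6e-08), a mean raised by Ovgp1-BPR GEMM replicate 1 at 799 CPM while the other 8 tumours lay at 1.45 to 27.9, whereas Pax8 was not called (0.43 ± 0.79, adjusted p = 0.71). Trim12a, a tripartite-motif gene of a family linked to innate immunity, rose to 25.2 CPM from 0.0494 in oviduct (adjusted p = 3.3e-09), and Mmp13, a collagenase, to 105 CPM from 0.202 (adjusted p = 2e-05). Trp53 was lower as an average (-1.16 ± 0.18, adjusted p = 2.9e-05), with Ovgp1-BPR tumours above the oviduct libraries and the others below.

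edgeR called 7463 of 20887 genes for oviduct-origin GEMM against oviduct, 3099 higher and 4364 lower, and 3868 with the models pooled as 1 group. The share higher was 41.5%, but 46.1% with DESeq2 and 49.3% with limma on TPM, so the size of the excess of lower genes depends on the method. Leaving out normal oviduct replicates 1 and 3 leaves 1 oviduct library, so no count is given for it. All 35 cell cycle and E2F genes rose (35 over the list alone), such as Mcm6 (4.04 ± 0.34) and E2f7 (3.90 ± 0.29), with camera adjusted p = 3.66e-29 and 0.0297 with an estimated correlation. Of 21 ciliated cell genes 18 fell (20 over the list alone), such as Dnah9 (-6.85 ± 0.75) and Rsph1 (-2.77 ± 0.37), with camera adjusted p = 4.78e-14 and 0.0297 with an estimated correlation. All 12 smooth muscle genes fell (12 over the list alone), such as Myh11 (-6.42 ± 0.69) and Cnn1 (-5.00 ± 0.62), with camera adjusted p = 3.42e-11 and 0.0297 with an estimated correlation. These 3 lists were the only ones of the 12 called that stayed called with an estimated correlation. The control is oviduct tissue with its muscle and ciliated cells (list means of 9.06 and 5.48 log2 CPM). Falls of the smooth muscle and ciliated lists therefore cannot be told apart from a difference in cell make-up. Of 20 homologous recombination and Fanconi repair genes 16 rose (16 over the list alone), with Polq at 3.19 ± 0.28 (camera adjusted p = 3.42e-11, adjusted p = 0.115 with an estimated correlation). Of 22 interferon response genes 12 rose (14 over the list alone), with Oasl1 at 3.95 ± 0.51 and Cxcl10 at 6.95 ± 1.11 (camera adjusted p = 5.79e-05, adjusted p = 0.416 with an estimated correlation). All 19 oocyte genes fell (19 over the list alone) relative to an oviduct in which replicates 1 and 3 carried oocyte transcripts, so that normal material, and not a loss in the tumour, can account for this fall (camera adjusted p = 8.9e-09, adjusted p = 0.276 with an estimated correlation). Human ovarian carcinoma subtype markers (4 of 12 up, 1 down, the same over the list alone, adjusted p = 0.151) and epithelial-mesenchymal transition factors (3 of 11 down, 3 over the list alone, adjusted p = 0.163) did not pass as lists.

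OSE-BPR GEMM (n = 3) against oviduct-origin GEMM tumours (n = 9) asked how primary tumours of the 2 sites differ. Pax8 was lower in OSE-BPR by a log2 fold change of -9.57 ± 1.55 (adjusted p = 0.00021, 0.166 against 131 CPM). Lhx9, a homeobox gene of the ovarian surface epithelium, was higher by 9.77 ± 1.34 (adjusted p = 3.9e-05, 446 against 0.83 CPM). Zim1 was higher by 11.62 ± 1.29 (adjusted p = 3.1e-06), Tdh by 11.53 ± 1.35 (adjusted p = 1e-05) and Cdh2, the neural cadherin, by 4.11 ± 0.70 (adjusted p = 0.00033). Gabrp, a GABA receptor subunit, had no count in the OSE-BPR tumours against a mean of 803 CPM and was at least 4400-fold lower, and Foxa2, an endoderm factor, at least 75.8-fold lower. Trp53 was lower (-1.73 ± 0.24, adjusted p = 3.9e-05) and Wt1 higher (1.44 ± 0.44, adjusted p = 0.02), with overlap of Wt1 between single tumours.

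edgeR called 5202 of 20000 genes between the GEMM tumours of the 2 origins, 2988 higher and 2214 lower in OSE-BPR. The share higher was 57.4%, but 49.9% with DESeq2 and 60.7% with limma on TPM, so an excess of higher genes depends on the method. The count was 1387 with the oviduct-origin models pooled as 1 group, 2695 without OSE-BPR GEMM replicate 3 and 3219 without replicate 2. Of 13 ovarian surface epithelium and mesothelium genes 10 rose (10 over the list alone), with Gata4 at 4.19 ± 0.65, Rspo1 at 3.31 ± 0.57 and Upk3b at 4.25 ± 0.74, though these 3 overlapped with Ovgp1-BPR tumours (camera adjusted p = 0.000199, adjusted p = 0.25 with an estimated correlation). Of 20 fibroblast and extracellular matrix genes 12 fell (13 over the list alone), such as Postn (-5.44 ± 1.10) and Thy1 (-3.70 ± 0.77), with camera adjusted p = 3.25e-07 (adjusted p = 0.25 with an estimated correlation). Of 15 macrophage genes 12 fell (12 over the list alone), with Adgre1 at -2.46 ± 0.54 and C1qb at -2.09 ± 0.48 (camera adjusted p = 2.35e-06, adjusted p = 0.34 with an estimated correlation). Of 11 B and plasma cell genes 9 fell (9 over the list alone), such as Cd79b (-4.06 ± 0.81), with a median of -6.00, or -4.08 with genes at their bounds (camera adjusted p = 0.000362, adjusted p = 0.34 with an estimated correlation). Of 11 neutrophil genes 8 fell (10 over the list alone), with S100a9 at -5.12 ± 1.28 (camera adjusted p = 0.000155, adjusted p = 0.25 with an estimated correlation). Ovgp1-BPR GEMM overlapped with OSE-BPR GEMM in the per-library mean of the fibroblast list (5.32 to 6.18 against 3.43 to 6.37 log2 CPM). The same held for the macrophage (3.29 to 5.27 against 2.1 to 4.24) and neutrophil lists (-1.55 to 0.295 against -2.16 to -0.643). It did not for B and plasma cells (-0.886 to 0.585 against -2.63 to -1.82). Ad-BPR and Pax8-BPR GEMM means were higher (fibroblast 8.49 and 8.2, macrophage 5.46 and 6.38, neutrophil 1.26 and 3.11). Of 20 high-grade serous carcinoma epithelial markers 8 fell (Cd24a -6.18 ± 1.29) and 2 rose (Muc16 2.67 ± 0.89), with the same counts over the list alone and camera adjusted p = 0.0165 (adjusted p = 0.34 with an estimated correlation). Cell cycle genes did not separate the origins (0 up, 1 down of 35, 0 over the list alone, adjusted p = 0.563). Camera called 12 of 25 lists, and 0 with an estimated correlation. Because every OSE-BPR tumour is FVB and every other tumour C57Bl/6, origin and strain cannot be separated in this comparison.

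**Figure D3:**
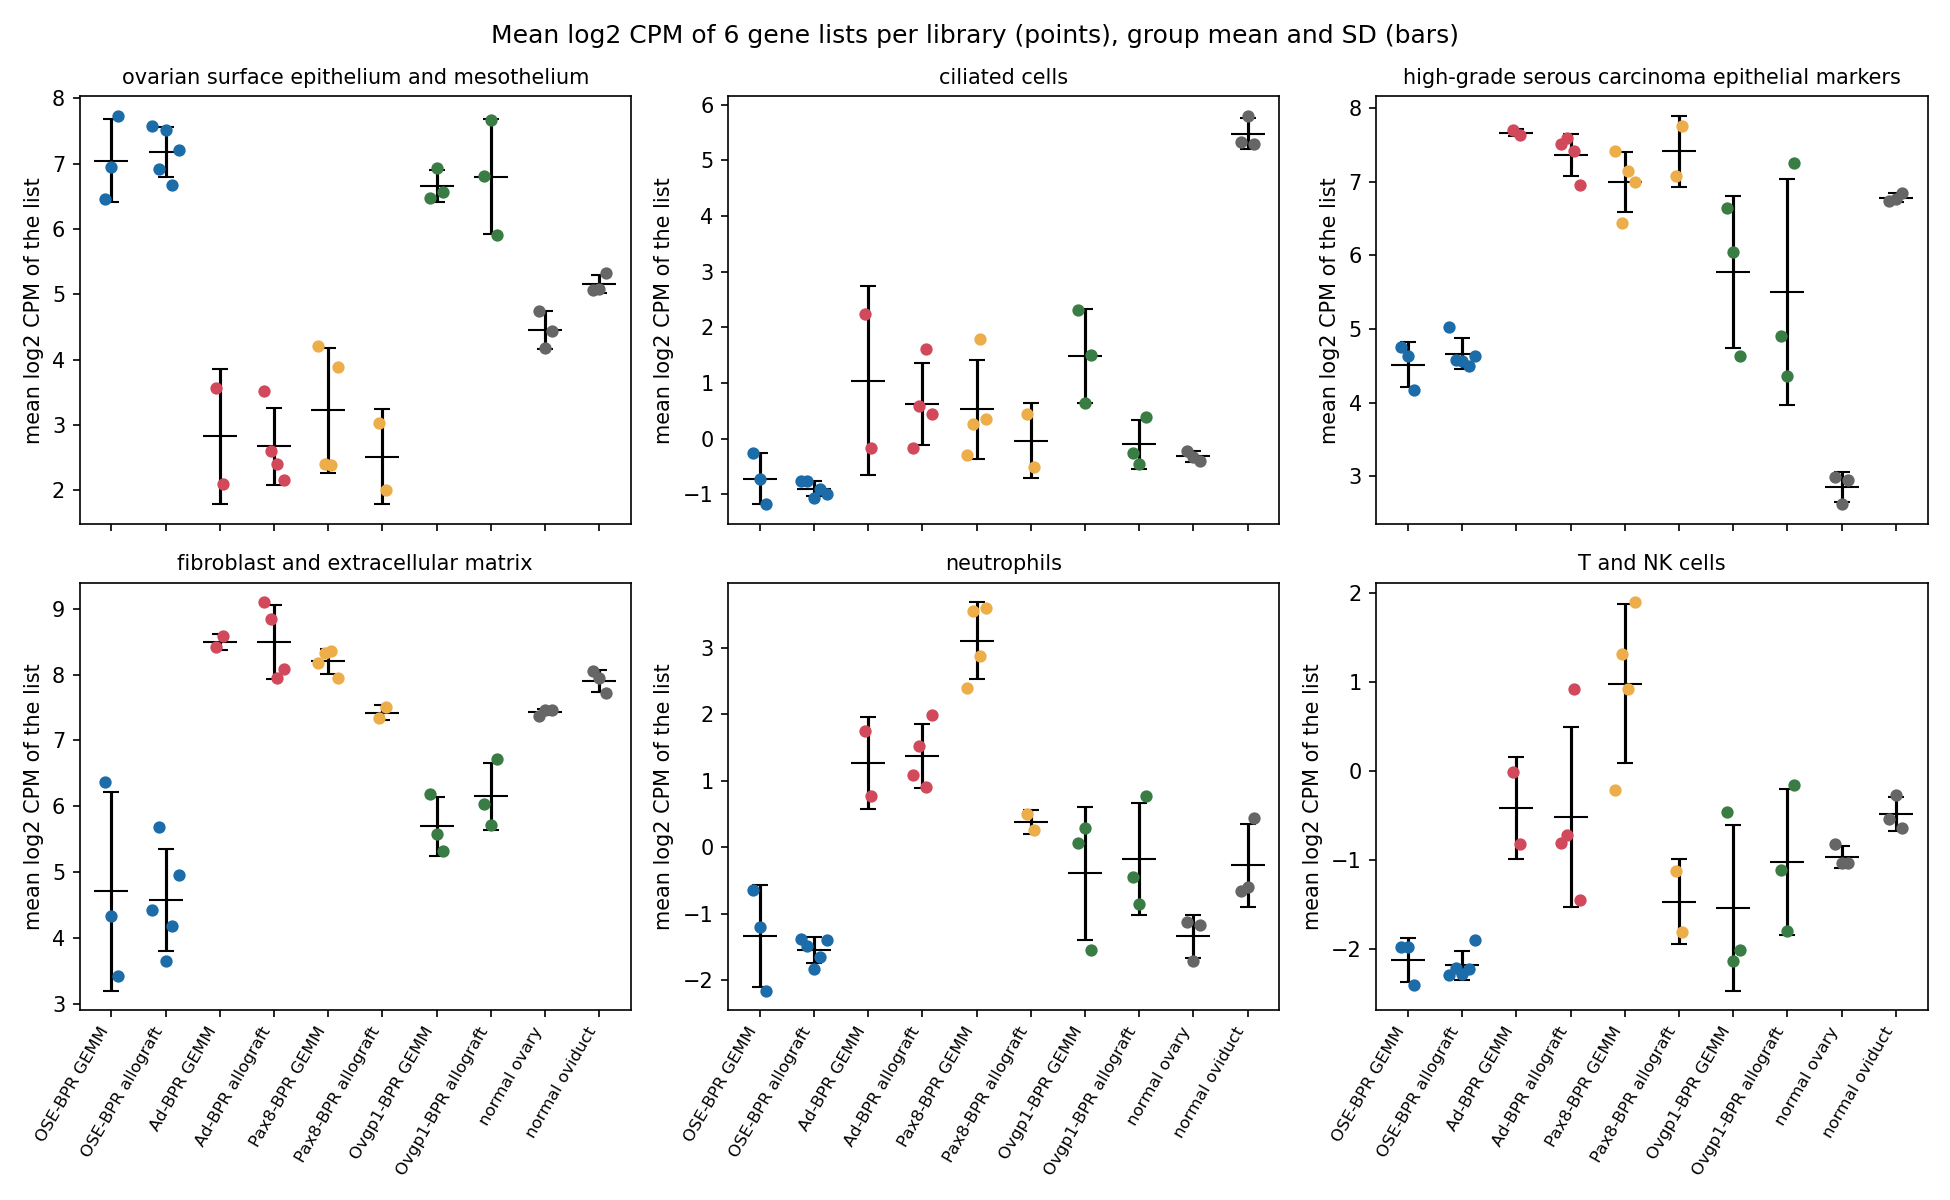
Mean log2 CPM of 6 gene lists in each library, by group, with bars for mean ± standard deviation (n per group 2 to 5).

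OSE-BPR allografts (n = 5) against oviduct-origin allografts (n = 9) asked whether the difference between origins is seen again in transplanted tumours. Pax8 was lower in OSE-BPR by -7.88 ± 1.10 (adjusted p = 2.1e-05, 0.423 against 105 CPM). Tdh was higher by 12.28 ± 1.37 (adjusted p = 3.7e-06) and Lhx9 by 8.65 ± 1.23 (adjusted p = 2.6e-05). Scn10a, a sodium channel subunit, had no count in the 9 oviduct-origin allografts and was at least 191-fold higher in OSE-BPR. Trim12a had no count in the 5 OSE-BPR allografts and was at least 162-fold lower. Wt1 was higher at 913 against 365 CPM (adjusted p = 0.0044, no overlap between single tumours).

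edgeR called 7554 of 20000 genes between the allografts of the 2 origins, 4076 higher and 3478 lower in OSE-BPR (5021 with the oviduct-origin models pooled as 1 group). The median log2 fold change of all genes was 0.11 with limma on TPM and 0.041 in the chosen fit. The share higher was 54%, but 50% with DESeq2 and 62% with limma on TPM, so an excess of higher genes depends on the method. Of the 2988 genes higher in the GEMM comparison 2539 were also higher here, and 1915 of 2214 lower genes were shared, with 0 in opposite directions. Across the 20000 genes the log2 fold changes of these 2 comparisons had a correlation of 0.887. Allografts may stem from the GEMM tumours compared, as OSE-BPR GEMM replicate 2 and allograft replicate 4 correlated at 0.989, so the comparisons need not be independent. Of 22 interferon response genes 16 fell (16 over the list alone, where 1 also rose), such as Oasl1 (-2.42 ± 0.33) and Ifit3 (-3.98 ± 0.70), with camera adjusted p = 8.12e-06 (adjusted p = 0.358 with an estimated correlation). Of 14 antigen presentation genes 9 fell (10 over the list alone), such as B2m (-2.58 ± 0.49) and H2-Eb1 (-5.94 ± 1.06), with camera adjusted p = 0.000458 (adjusted p = 0.385 with an estimated correlation). Of 12 endothelium genes 7 fell (7 over the list alone), with Vwf at -4.22 ± 0.49, and 1 rose (2 over the list alone), Kdr at 1.29 ± 0.33, which also overlapped between tumours (camera adjusted p = 0.0117, adjusted p = 0.358 with an estimated correlation). Of 17 T and NK cell genes 8 fell (8 over the list alone), such as Cd4 (-2.33 ± 0.52), with a median of -2.88, or -1.26 with genes at their bounds (camera adjusted p = 0.00233, adjusted p = 0.39 with an estimated correlation). Ovarian surface epithelium and mesothelium genes rose in 10 of 13 cases (10 over the list alone), with Upk3b at 5.37 ± 0.75 (camera adjusted p = 0.000298, adjusted p = 0.269 with an estimated correlation). Of 5 pancreatic acinar genes 2 rose, Pnlip (8.56 ± 0.85) and Cela3b (7.63 ± 1.10), and 3 over the list alone (camera adjusted p = 0.0261, adjusted p = 0.358 with an estimated correlation). Camera called 15 of 25 lists and 0 with an estimated correlation, and strain is again tied to origin.

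Whether the origin difference itself changes on transplantation was asked by subtracting the GEMM difference from the allograft difference (all 26 tumours). No gene was called by edgeR (0 of 20000, 443 at unadjusted p < 0.05), against 14 by DESeq2, 0 by limma on TPM and 0 by limma voom. For the erythroid list the difference of OSE-BPR from oviduct-origin tumours was lower in allografts than in GEMM, with all 7 genes negative, a median of -2.08 and camera adjusted p = 6.91e-07 (adjusted p = 0.615 with an estimated correlation). Its mean log2 CPM was 3.54 in GEMM and 2.78 in allografts of OSE-BPR, but 2.12 and 2.86 in Ad-BPR, 3.88 and 5.27 in Pax8-BPR and 3.37 and 4.88 in Ovgp1-BPR. Interferon response genes had a median of -0.61 over 22 genes (camera adjusted p = 0.000527, adjusted p = 0.849 with an estimated correlation). Skeletal muscle genes had a median of -3.83 over 10 genes (0 called, 2 down over the list alone, camera adjusted p = 0.00777, adjusted p = 0.849 with an estimated correlation). This list was high in single allografts, Ad-BPR replicate 1 (mean log2 CPM 5.55), Pax8-BPR replicate 2 (3.66) and Ovgp1-BPR replicate 3 (1.06), and at most -0.259 in the other 23 tumours. The ovarian surface epithelium and mesothelium list had a median of 0.40 and did not pass (adjusted p = 0.408). Camera called 7 of 25 lists, and 0 with an estimated correlation.

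Pax8-BPR (n = 4) against Ad-BPR GEMM tumours (n = 2) asked whether the way the oviduct was targeted matters. Trp53 was 30 against 15.7 CPM (0.94 ± 0.29, adjusted p = 0.52), Pax8 105 against 131 (-0.31 ± 1.07, adjusted p = 0.97) and Wt1 202 against 253 (-0.33 ± 0.59, adjusted p = 0.93). No gene was called by edgeR (0 of 20000, 1531 at unadjusted p < 0.05, smallest adjusted p = 0.0946), against 52 by DESeq2, 16 by limma on TPM and 16 by limma voom, and edgeR called 3 without Pax8-BPR GEMM replicate 1. Immune lists stood higher in Pax8-BPR, although 0 of their genes were called, also over each list alone. The interferon response list was positive in 22 of 22 genes, with a median of 1.40 (camera adjusted p = 1.45e-09, adjusted p = 0.343 with an estimated correlation). B and plasma cell genes had a median of 2.85 (camera adjusted p = 6e-08, adjusted p = 0.178 with an estimated correlation) and T and NK cell genes of 1.84 (camera adjusted p = 8.62e-08, adjusted p = 0.343 with an estimated correlation). Neutrophil genes had a median of 1.66 (camera adjusted p = 2.46e-08, adjusted p = 0.137 with an estimated correlation). Camera called 9 of 25 lists and 0 with an estimated correlation. With 2 Ad-BPR tumours, 10.4% of simulated 2-fold and 78.8% of simulated 16-fold changes were found, so moderate differences can go unseen.

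Ovgp1-BPR (n = 3) against Pax8-BPR GEMM tumours (n = 4) asked how tumours from the 2 secretory-cell drivers differ. Trp53 was higher in Ovgp1-BPR by 2.09 ± 0.24 (adjusted p = 3.5e-05, 128 against 30 CPM). Nell1, a secreted protein that promotes bone formation, was higher by 9.13 ± 1.17 (adjusted p = 0.00017, 214 against 0.373 CPM), and Gabrq, a GABA receptor subunit, by 8.72 ± 1.22 (adjusted p = 0.00017). Sesn1, a stress-response target of p53, rose by 2.74 ± 0.31 (adjusted p = 3.3e-05, 121 against 18.1 CPM), but it was the 1 gene called among 20 p53 targets (1 over the list alone), whose median was -0.37 (camera adjusted p = 0.703). Krt5, a keratin of stratified epithelium, was at 0.158 against 206 CPM (-10.25 ± 2.39, adjusted p = 0.0081), and Krt6a at 0.264 against 464 CPM (-10.71 ± 2.42, adjusted p = 0.0052). Wt1 rose by 1.71 ± 0.53 (adjusted p = 0.025), Ovgp1 by 6.10 ± 1.05 (adjusted p = 0.00085, with a range of 26.2 to 796 CPM among the Ovgp1-BPR tumours), and Pax8 was not called (adjusted p = 0.69).

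edgeR called 4493 of 20000 genes for Ovgp1-BPR against Pax8-BPR, 2248 higher and 2245 lower. The share higher was 50%, and 67.7% by limma on TPM. The median log2 fold change of all genes was 0.15 with limma on TPM and -0.059 in the chosen fit. The Cre driver and the Trp53 allele change together here, so their parts cannot be separated. The count was 1856 in a fit of only these groups, 1597 without Ovgp1-BPR GEMM replicate 3 and 2062 without replicate 2. Of 13 ovarian surface epithelium and mesothelium genes 10 rose, such as Nkain4 (5.35 ± 0.66), Lrrn4 (6.58 ± 1.21) and Upk3b (5.55 ± 1.00, chromosome 5, 136038496 to 136046487, ENSMUSG00000042985.7), and 2 fell, Krt19 (-2.68 ± 0.65) and Msln (-3.02 ± 1.07), with the same counts over the list alone and camera adjusted p = 7.22e-06 (adjusted p = 0.169 with an estimated correlation). Of 11 neutrophil genes 10 fell (10 over the list alone), such as Mmp8 (-4.19 ± 0.87) and S100a8 (-4.45 ± 1.20), with camera adjusted p = 1e-07 (adjusted p = 0.169 with an estimated correlation). Of 15 macrophage genes 11 fell (12 over the list alone), with Cd68 at -2.12 ± 0.50 and C1qa at -2.01 ± 0.51 (camera adjusted p = 1e-07, adjusted p = 0.222 with an estimated correlation). Of 20 fibroblast and extracellular matrix genes 10 fell (12 over the list alone, where 1 also rose), with Col5a2 at -3.58 ± 0.51 (camera adjusted p = 1.57e-06, adjusted p = 0.222 with an estimated correlation). Oviduct secretory genes did not pass as a list (adjusted p = 0.575), with 2 up (Emx2 3.03 ± 0.53), 1 down (Wnt7a, 0.451 against 64.3 CPM) and the same counts over the list alone. Their median (-0.73) and mean (-0.13) were negative while the direction of the test was up. Camera called 12 of 25 lists and 0 with an estimated correlation.

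Ovgp1-BPR (n = 3) against Ad-BPR GEMM tumours (n = 2) asked the same with the adenoviral model. Trp53 was higher by 3.03 ± 0.33 (adjusted p = 0.00016, 128 against 15.7 CPM) and Sesn1 by 2.47 ± 0.40 (adjusted p = 0.0014). The p53 target list did not pass here either (2 up, 1 down of 20, the same over the list alone, adjusted p = 0.982), with a median of -0.20 but a positive mean (0.13) and test direction. Upk3b was higher at 906 against 5.14 CPM (adjusted p = 0.0057), Gata4, a gonadal factor, by 6.23 ± 1.24 (adjusted p = 0.0055) and Nkain4 by 6.06 ± 0.94 (adjusted p = 0.0013). Slc26a4, an anion exchanger, had no count in Ovgp1-BPR against 34.5 CPM and was at least 211-fold lower, and Col5a2 fell by 4.00 ± 0.55 on the log2 scale (adjusted p = 0.00074).

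edgeR called 2088 of 20000 genes for Ovgp1-BPR against Ad-BPR, 1018 higher and 1070 lower. The share higher was 48.8%, and 62.9% by limma on TPM. The median log2 fold change of all genes was 0.11 with limma on TPM and 0.024 in the chosen fit. The count was 1066 in a fit of only these groups, 606 without Ovgp1-BPR GEMM replicate 3 and 835 without Ovgp1-BPR GEMM replicate 2. It was 89 without Ad-BPR GEMM replicate 2 and 552 without Ad-BPR GEMM replicate 1, each of which leaves 1 Ad-BPR tumour that is assumed to vary like the other groups. Of 13 ovarian surface epithelium and mesothelium genes 8 rose and 1 fell (Krt19, -2.87 ± 0.72), with the same counts over the list alone and camera adjusted p = 0.000217 (adjusted p = 0.296 with an estimated correlation). Of 20 fibroblast and extracellular matrix genes 10 fell (13 over the list alone, where 1 also rose), such as Col1a1 (-4.50 ± 1.12), with camera adjusted p = 1.8e-07 (adjusted p = 0.296 with an estimated correlation). Of 20 high-grade serous carcinoma epithelial markers 1 fell, Krt19 (1 over the list alone), and the list passed at camera adjusted p = 0.00608 (adjusted p = 0.703 with an estimated correlation). Camera called 7 of 25 lists and 0 with an estimated correlation.

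OSE-BPR allografts (n = 5) against OSE-BPR GEMM tumours (n = 3) asked what transplantation changes in this model. Trp53 was 12.7 against 11.8 CPM (0.11 ± 0.23), Wt1 913 against 878 (0.06 ± 0.50) and Cdkn2a 164 against 216 (-0.39 ± 0.29), all with adjusted p = 1. No gene was called by edgeR (0 of 20000, 457 at unadjusted p < 0.05), against 12 by DESeq2, 0 by limma on TPM and 0 by limma voom. Allografts may stem from these GEMM tumours (GEMM replicate 2 and allograft replicate 4 correlated at 0.989), and the fit ignores such pairs. Cell cycle and E2F genes stood higher in allografts, with 34 of 35 positive and a median of 0.38 (camera adjusted p = 1.22e-12, adjusted p = 0.467 with an estimated correlation). Endothelium genes stood lower, with a median of -0.49 and 2 of 12 down over the list alone (camera adjusted p = 0.000221, adjusted p = 0.467 with an estimated correlation). Camera called 7 of 25 lists and 0 with an estimated correlation.

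Ad-BPR allografts (n = 4) against Ad-BPR GEMM tumours (n = 2) asked the same of the adenoviral oviduct model. Trp53 was 19.1 against 15.7 CPM (0.28 ± 0.28), Pax8 95.1 against 131 (-0.46 ± 1.07) and Krt18 1150 against 827 (0.48 ± 0.58), all with adjusted p = 1. The 4 allografts do not lie near that Pax8 mean, as replicate 2 stood at 167 CPM (replicate 1 slightly higher) and replicates 3 and 4 at 23.2 and 19.6, which were also low in Xist (113 and 143 CPM against 1550 and 984 in replicates 1 and 2). Among 20000 genes edgeR called 0 (352 at unadjusted p < 0.05), against 11 by DESeq2, 0 by limma on TPM and 1 by limma voom. GEMM replicate 2 and allograft replicate 2 correlated at 0.979, and the fit ignores such possible pairs too. Skeletal muscle genes had a median of 7.64, or 5.83 with genes at their bounds, and 8 of 10 were higher over the list alone (camera adjusted p = 9.47e-05, adjusted p = 0.818 with an estimated correlation). This stems from allograft replicate 1, whose mean over the list was 5.55 log2 CPM against -0.7 in the next library. Macrophage genes had a median of 0.57 (0 called, camera adjusted p = 0.00306, adjusted p = 0.818 with an estimated correlation). Camera called 5 of 25 lists and 0 with an estimated correlation.

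Pax8-BPR allografts (n = 2) against Pax8-BPR GEMM tumours (n = 4) asked the same of the Pax8-driven model. Trp53 was 15.7 against 30 CPM (-0.94 ± 0.29, adjusted p = 0.16), Pax8 90.1 against 105 (-0.22 ± 1.09, adjusted p = 0.95) and Cdkn2a 175 against 268 (-0.62 ± 0.36, adjusted p = 0.43). edgeR called 0 of 20000 genes (2978 at unadjusted p < 0.05, smallest adjusted p = 0.062), against 731 by DESeq2, 112 by limma on TPM and 9 by limma voom, and edgeR called 117 without Pax8-BPR allograft replicate 1 (which leaves 1 allograft, assumed to vary like the other groups) and 5, 2, 1 and 9 without GEMM replicates 1 to 4. T and NK cell genes stood lower in allografts in 17 of 17 cases, with a median of -3.52 and 8 down over the list alone (camera adjusted p = 1.18e-11, adjusted p = 0.157 with an estimated correlation). Neutrophil genes had a median of -2.82 and 8 of 11 down over the list alone (camera adjusted p = 2.01e-10, adjusted p = 0.0636 with an estimated correlation). Macrophage genes had a median of -1.54 and 8 of 15 down over the list alone (camera adjusted p = 6.34e-09, adjusted p = 0.22 with an estimated correlation). Cell cycle and E2F genes stood higher, with a median of 0.62 and 6 of 35 up over the list alone (camera adjusted p = 1.99e-13, adjusted p = 0.213 with an estimated correlation). Camera called 13 of 25 lists and 0 with an estimated correlation. With 2 allografts, 2.99% of simulated 2-fold and 69.7% of simulated 16-fold changes were found.

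Ovgp1-BPR allografts (n = 3) against Ovgp1-BPR GEMM tumours (n = 3) asked the same of the Ovgp1-driven model. Trp53 was 125 against 128 CPM (-0.04 ± 0.26), Pax8 130 against 156 (-0.26 ± 1.02) and Wt1 628 against 662 (-0.08 ± 0.56), all with adjusted p = 1. Ovgp1 was 24.7 against 283 CPM (-3.52 ± 1.05, adjusted p = 1), a GEMM mean that rests on replicate 1, as the 3 GEMM tumours stood at 799, 26.3 and 27.9 CPM. Of 20000 genes 0 were called by edgeR (419 at unadjusted p < 0.05), against 9 by DESeq2, 1 by limma on TPM and 1 by limma voom. Each GEMM tumour had an allograft as mutual nearest tumour (0.969, 0.97 and 0.978 for GEMM replicates 1 to 3), and the fit ignores such pairs. A change within pairs can thus be hidden by the spread between tumours. Ciliated cell genes stood lower in allografts, with a median of -1.74 over 19 genes, 0 of them called (camera adjusted p = 2.72e-12, adjusted p = 0.103 with an estimated correlation). Interferon response genes stood higher in 22 of 22 cases, with a median of 0.68 (camera adjusted p = 2.98e-12, adjusted p = 0.22 with an estimated correlation). Adipocyte genes had a median of 5.45, or 4.42 with genes at their bounds (0 called, camera adjusted p = 4.35e-06, adjusted p = 0.22 with an estimated correlation). Camera called 10 of 25 lists and 0 with an estimated correlation.

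Allografts (n = 14) against GEMM tumours (n = 12) with the 4 models weighted equally asked for a change common to all models. Trp53 was 43.1 against 46.4 CPM (-0.14 ± 0.13, adjusted p = 0.92), Cdkn2a 179 against 221 (-0.30 ± 0.16, adjusted p = 0.83) and Wt1 502 against 499 (0.01 ± 0.28, adjusted p = 1). The common change held 0 of 20000 genes called by edgeR (1210 at unadjusted p < 0.05, smallest adjusted p = 0.429), against 34 by DESeq2, 0 by limma on TPM and 1 by limma voom. Cell cycle and E2F genes stood higher in allografts in 35 of 35 cases, with a median of 0.26 and 2 up over the list alone (camera adjusted p = 1.3e-16, adjusted p = 0.339 with an estimated correlation). The list mean (log2 CPM) was 6.11 in GEMM and 6.49 in allografts of OSE-BPR, 6.03 and 6.79 in Pax8-BPR and 6.04 and 6.15 in Ad-BPR, but 6.36 and 6.32 in Ovgp1-BPR. Homologous recombination and Fanconi repair genes had a median of 0.23 and means of 4.52 and 4.81 in OSE-BPR, 4.17 and 4.81 in Pax8-BPR, 4.24 and 4.33 in Ad-BPR and 4.37 and 4.31 in Ovgp1-BPR (0 called, camera adjusted p = 6.5e-06, adjusted p = 0.339 with an estimated correlation). Skeletal muscle genes had a median of 3.53 and 9 of 10 up over the list alone (camera adjusted p = 1.46e-05, adjusted p = 0.339 with an estimated correlation). Single allografts carry this list (Ad-BPR replicate 1 at 5.55 mean log2 CPM, Pax8-BPR replicate 2 at 3.66 and Ovgp1-BPR replicate 3 at 1.06), and OSE-BPR means were -0.855 in allografts and -0.994 in GEMM, so it is no change common to the models. Neutrophil genes stood lower in 11 of 11 cases, with a median of -0.78 (camera adjusted p = 0.000503, adjusted p = 0.339 with an estimated correlation). This stems from Pax8-BPR (list mean 3.11 in GEMM and 0.378 in allografts), as it was -1.33 and -1.55 in OSE-BPR, 1.26 and 1.37 in Ad-BPR and -0.395 and -0.177 in Ovgp1-BPR. Camera called 11 of 25 lists and 0 with an estimated correlation.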

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

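The tests of ovarian RNA in the normal oviduct, of cumulus-oocyte complexes, of exchanged tumours and of fewer stromal cells were chosen only after the result was seen. The other tests here were chosen before it.

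Other splits of the same libraries were fitted for comparisons of at least 3 against 3. The real split called more genes than any other split drawn for oviduct-origin GEMM against oviduct (7463 genes, highest of the other splits 2403, 1 of 60 drawn splits as large). The same held for origin in GEMM (5202 against 1839, 1 of 60), origin in allografts (7554 against 1559, 1 of 60) and Ovgp1-BPR against Pax8-BPR GEMM (4493 against 2272, 1 of 35). The other splits mix groups that differ from each other, which widens the spread within their arms. The lead of the real split therefore does not exclude chance. For normal oviduct against ovary (9191 against 0, 1 of 10) and OSE-BPR GEMM against ovary (4842 against 0, 1 of 10) the splits are too few for a share under 0.05. With a real count of 0 every split calls at least as many genes, so this test decides nothing for the change of the origin difference (highest other split 384, 20 of 20), OSE-BPR allograft against GEMM (1016, 20 of 20), Ovgp1-BPR allograft against GEMM (113, 10 of 10) and allograft against GEMM across models (2, 20 of 20). In these 4 comparisons edgeR gave 443, 457, 419 and 1210 genes at unadjusted p < 0.05, and DESeq2 14, 12, 9 and 34. What the highest of these splits separates was not tested.

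Single libraries stood apart from the rest of their group in 12 of 108 runs of Dixon's gap test, where chance alone gives about 1 in 20, or 5.4. Lists and single genes were tested in the 3 groups with 4 or 5 libraries (OSE-BPR allografts, Ad-BPR allografts and Pax8-BPR GEMM), and groups of 2 or 3 were not tested. In Pax8-BPR GEMM replicate 1 the homologous recombination list was low (mean log2 CPM 3.48, next 4.35) and the granulosa list high (2.75, next 0.0354). Wt1 in Pax8-BPR GEMM replicate 2 was low at 3.78 as log2(CPM + 1) (next 7.75), and endothelium in replicate 4 was low (4.03, next 4.96). In OSE-BPR allografts, replicate 1 was high in the high-grade serous carcinoma markers (5.03, next 4.64) and in Pax8 (1.64, next 0), replicate 2 in adipocytes (2.15, next -0.192), and replicate 5 in T and NK cells (-1.9, next -2.22). Replicate 3 was low in the subtype markers (1.93, next 2.79) and replicate 4 in Xist (10.6, next 11.1). In Ad-BPR allografts, replicate 1 was high in skeletal muscle (5.55, next -0.7) and replicate 3 in Epcam (10, next 9.7).

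The test of whether the origin difference changes between GEMM and allografts called 7 lists by camera. Erythroid cells passed at adjusted p = 6.91e-07 (adjusted p = 0.615 with an estimated correlation) and pancreatic acinar cells at 0.0241 (adjusted p = 0.615 with an estimated correlation). Interferon response passed at 0.000527, antigen presentation at 0.00777, skeletal muscle at 0.00777, B and plasma cells at 0.0456 and endothelium at 0.0456 (each adjusted p = 0.849 with an estimated correlation).

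Transcripts of granulosa cells and oocytes were higher in normal oviduct replicates 1 and 3 (mean log2 CPM of the lists 6.05 and 5.07 for granulosa, 3.34 and 3.03 for oocyte) than in replicate 2 (1.76 and -0.932). RNA of ovarian tissue in these libraries needs theca and luteal, granulosa and oocyte genes to be raised together, and the lowest of the 6 median shares of the ovary level was 3.67%. The shares were 15.9% and 9.67% for granulosa genes (9 genes), 12.6% and 3.67% for theca and luteal genes (6) and 32.8% and 26.9% for oocyte genes (16) in replicates 1 and 3. Ovulated oocytes with their cumulus cells, which would lack theca and luteal transcripts, remain open because the ratio of the theca and luteal share to the oocyte share was 0.384 in replicate 1 and 0.136 in replicate 3. Both may contribute, and a true fall of these genes in oviduct-origin tumours cannot be read from this control.

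Ovgp1-BPR tumours shared high levels of most mesothelial genes with OSE-BPR tumours, though not of Msln (medians of 44.6 and 42.7 CPM against 154 in Ad-BPR and 198 in Pax8-BPR). An exchange of tumours between the models is argued against by Trp53, whose lowest level in the 6 Ovgp1-BPR tumours (101 CPM) lay above the highest in OSE-BPR (15.7), and by Pax8 (83.7 against 2.12). Fewer stromal and immune cells would raise epithelial genes too, but the epithelial marker list had a median of -1.29 against Pax8-BPR GEMM while the mesothelial list had 3.84. Epithelial genes may be low in the tumour cells themselves (Epcam 83 against 1090 CPM), so this list cannot gauge the share of other cells. The fibroblast, macrophage and neutrophil lists were lower in Ovgp1-BPR GEMM (mean log2 CPM 5.69, 4.19 and -0.395 against 8.2, 6.38 and 3.11), so fewer such cells are not excluded. Calls of OSE-BPR allografts and of Ovgp1-BPR GEMM tumours against Ad-BPR and Pax8-BPR overlapped at 3.01 times the number for independent lists among higher genes (1696 against 562.6) and 3.44 times among lower genes (1448 against 420.8), but both have the same models as reference, so a set of genes shared with OSE-BPR cannot be told apart from features of Ad-BPR and Pax8-BPR. The cell targeted by the Ovgp1 driver, the R172H allele and other unmeasured differences of this model stay open.

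OSE-BPR and oviduct-origin tumours differ in many genes (5202 called in GEMM and 7554 in allografts), and they also differ in strain. If the strain labels hold, strain as the whole cause is argued against by the same overlap of 3.01, since 1696 of 4508 genes higher and 1448 of 4113 genes lower in OSE-BPR allografts than in Ad-BPR and Pax8-BPR allografts were called in the same direction (36 and 38 in the opposite one) in Ovgp1-BPR GEMM against Ad-BPR and Pax8-BPR GEMM, all C57Bl/6 by label. Both comparisons have Ad-BPR and Pax8-BPR as reference and may share tumour sources, so an overlap above that of independent lists may be partly built in. The argument covers only the genes called in both. It does not cover the other genes, such as those that set OSE-BPR apart from all 3 oviduct-origin models. Strain background that differs from the labels was not tested. Strain as the cause of a part cannot be told apart from origin, because 0 strains hold tumours of both origins.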

How the results depend on the processing

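The alternative without normal oviduct replicates 1 and 3 was chosen after seeing the data, and all other alternatives here were chosen before the data were examined. A change of direction was counted only for a gene called in the chosen fit or in the alternative. A value without an adjusted p and with the same direction was counted as kept. By this rule, among 739 values for named genes the direction and call were kept in 729 with DESeq2, 738 with RLE factors, 713 with limma voom, 705 without a filter and 686 with limma on TPM. The exceptions with these 5 lost or gained a call without such a change of direction. Leaving out 1 library kept 6305 of 6937 such values, with 628 lost and 4 gained. The fit of all 32 libraries kept 56 of 117 (61 lost), pooled models 226 of 326 (98 lost, 2 with a change of direction), and fits of only the groups compared 530 of 594 (63 lost, 1 gained). Without normal oviduct replicates 1 and 3 the call was lost in 51 of 224 and the direction changed in 1.

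For normal oviduct against ovary (9191 genes) the paired fit with the animal as a replicate block called 7971, kept 110 of 117 named genes with 7 lost, and left 24 of 25 list calls as they were with 1 gained. The fit of all 32 libraries called 2605. Without normal oviduct replicates 1 and 3 a lone oviduct library is left, with all spread taken from the ovaries, so no count is given. OSE-BPR GEMM against ovary (4842) gave 9901 with limma voom, and 3114 (without normal ovary replicate 2) to 4934 (without OSE-BPR GEMM replicate 1). Oviduct-origin GEMM against oviduct (7463) gave 11795 with limma voom, 3868 with the models pooled and 2597 without normal oviduct replicates 1 and 3, which leaves a lone oviduct library assumed to vary like the other groups.

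OSE-BPR against oviduct-origin GEMM (5202) gave 8273 with limma voom, 1387 pooled, and 2695 (without OSE-BPR GEMM replicate 3) to 5663 (without Pax8-BPR GEMM replicate 2). The same in allografts (7554) gave 5021 pooled. The change of the origin difference (0 with edgeR, 443 at unadjusted p < 0.05) gave 14 with DESeq2 and 0 with limma on TPM or voom. Fits of only the groups compared are the same as the chosen fit for this comparison and for allografts against GEMM across models.

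Pax8-BPR against Ad-BPR GEMM (0 with edgeR, 1531 unadjusted) gave 52 with DESeq2, 16 with limma on TPM and 16 with limma voom, and 0 to 3 on leaving out 1 library, the 3 without Pax8-BPR GEMM replicate 1. Ovgp1-BPR against Pax8-BPR GEMM (4493) gave 1856 with only the groups compared, and 1597 (without Ovgp1-BPR GEMM replicate 3; 2062 without replicate 2) to 4939 (without Ovgp1-BPR GEMM replicate 1). Ovgp1-BPR against Ad-BPR GEMM (2088) gave 3517 with DESeq2, 5554 with limma voom, 1066 with only the groups compared, and 89 (without Ad-BPR GEMM replicate 2, which leaves a lone Ad-BPR tumour assumed to vary like the other groups) to 2591 (without Ovgp1-BPR GEMM replicate 1).

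Allograft against GEMM gave 0 with edgeR in each model and across the 4 models. No fit with an allograft paired to its source tumour was run, as the labels do not name the source. DESeq2 gave 12 in OSE-BPR, 11 in Ad-BPR, 731 in Pax8-BPR, 9 in Ovgp1-BPR and 34 across models. Limma voom gave 0 in OSE-BPR, 1 in Ad-BPR, 9 in Pax8-BPR, 1 in Ovgp1-BPR and 1 across models, and limma on TPM gave 112 in Pax8-BPR, 1 in Ovgp1-BPR and 0 in the others. At unadjusted p < 0.05 edgeR gave 457, 352, 2978, 419 and 1210. Leaving out 1 library gave 0 to 117 in Pax8-BPR (117 without Pax8-BPR allograft replicate 1, which leaves a lone allograft, and 5, 2, 1 and 9 without GEMM replicates 1 to 4) and 0 in the others.

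Of the 350 list results camera called 142, and 3 with an estimated correlation, 93 with directional fry, 125 with mixed fry and 150 without a filter. Among genes called in the chosen fit or in the alternative, a change of direction was counted in 3 values for named genes, all in oviduct-origin GEMM against oviduct. Cpa1, a pancreatic enzyme, went from -3.62 to 4.29 (4.288) without normal oviduct replicates 1 and 3. With the models pooled Nkain4 went from -1.90 to 0.39 and Upk3b from -1.84 to 0.978, because Ovgp1-BPR tumours hold far more of both than the other models. Within-model similarity differed from between-model similarity by 0.0611 to 0.0791 in GEMM and 0.0831 to 0.1 in allografts on leaving out 1 tumour.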

Other observations

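The tests below of genes singled out here, Trim12a, Nell1, Ifi202b, Krt5, Krt6a, Upk3b, Lrrn4, Msln, Peg3, Zim1, Usp29, Igf2 and H19, were chosen only after their values were seen, while the test of the other imprinted genes was chosen before its result was seen. Krt5 and Krt6a, keratins of stratified epithelium, varied between the models with overlap. Krt5 lay at 7.31 to 936 CPM in the 6 Pax8-BPR tumours and 0.796 to 140 in the 6 Ad-BPR tumours, but at most 1.94 in the 8 OSE-BPR and 0.514 in the 6 Ovgp1-BPR tumours. Krt6a lay at 220 to 701 CPM in Ad-BPR and 3.64 to 1080 in Pax8-BPR, against at most 0.536 in OSE-BPR and 87.9 in Ovgp1-BPR. Upk3b, a uroplakin of mesothelium, was at 515 to 1240 CPM in OSE-BPR and 277 to 2000 in Ovgp1-BPR, against 0.333 to 26.9 in Ad-BPR and Pax8-BPR together. Lrrn4, another mesothelial gene, was at 37.9 to 285 in OSE-BPR, 58.2 to 666 in Ovgp1-BPR and at most 6.14 in Ad-BPR and Pax8-BPR. Msln went the other way, with medians of 42.7 in OSE-BPR, 44.6 in Ovgp1-BPR and 154 in Ad-BPR and Pax8-BPR together.

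Nell1 was at 36.4 to 386 CPM in the 6 Ovgp1-BPR tumours and at most 1.21 in the 20 others, and 0.901 to 3.66 in normal tissue. Trim12a was at 12 to 56.2 CPM in the 18 oviduct-origin tumours, at most 0.122 in the 8 OSE-BPR tumours and at most 0.0962 in the 6 normal libraries. The normal libraries are C57Bl/6 by label like the oviduct-origin tumours, so this gene does not follow the labelled strain alone. Ifi202b, an interferon-inducible gene, had a median of 0 in Ovgp1-BPR (0 to 3.36 CPM), 8.71 in the 20 other tumours (0.0551 to 48.7, overlapping) and 13.7 to 27.6 in normal tissue. Whether these differences come from strain background carried along with the engineered alleles was not tested.

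A group of imprinted genes was high in OSE-BPR tumours. Peg3 was at 530 to 2700 CPM in the 8 OSE-BPR tumours and at most 151 in the 18 others, Zim1 at 16.6 to 726 against at most 3.09, Usp29 at 20 to 97.5 against at most 4.35, and Igf2 at 40.5 to 3490 against at most 49.6. H19 was at 68.8 to 844 in OSE-BPR and reached 580 in Pax8-BPR. Whether imprinted genes as a class are raised, leaving out the 5 genes seen first, was tested on 35 of 37 listed genes. The higher of the p values by camera was 0.0617 (allografts, median log2 fold change 0.32, 15 higher and 5 lower) and the other 0.0315 (GEMM, median 0.68, 11 higher and 3 lower). With an estimated correlation they were 0.111 and 0.0716, so a rise of the class was not borne out by its test.

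Genes called in OSE-BPR against oviduct-origin GEMM overlapped in part with genes that separate the normal tissues. Of the genes higher in OSE-BPR 812 were also higher in normal ovary than in normal oviduct, against 587.7 for independent lists, while 444 went in the opposite direction. Of the lower genes 957 were shared against 536, with 236 opposite, and the log2 fold changes had a correlation of 0.384. The tumours compared also differ in strain and the normal tissues in cell make-up, and oviduct replicates 1 and 3 carried ovarian transcripts. The overlap alone therefore does not show that tumours kept genes of their tissue of origin.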
